A study of Mus musculus with 4 samples.

How the data were processed

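Gene expression was measured on Affymetrix mouse Gene 1.0 ST arrays in cultures of cortical neurons from newborn mice (postnatal day 0) of a mixed SV129 and C57BL/6 background. Per the labels, the pups were Syt1-deficient or wild type, without a statement of which array came from which. Cultures were infected at 5 days in vitro with control lentivirus, with lentivirus carrying shRNAs against calmodulin, or with those shRNAs together with a wild-type calmodulin that the shRNAs do not target. RNA was taken at 14 to 15 days in vitro. The values used were 4 columns, from 2 knockdown and 2 rescue samples, numbered here as repeat 1 and repeat 2.

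Each value was a linear ratio that the authors deposited, of the test array over the control array of the same repeat, per the labels and the series design text. The 2 control arrays were not analysed here. Background correction, summarization and normalization between arrays were not given in the sources used here, nor was a genome build, so no coordinates are printed. The ratios carry no intensities, so dim probe sets could not be set apart, and the number of arrays limits the precision. Column medians of the ratios were 1.004 and 1.006 in the knockdown and 0.9952 and 0.996 in the rescue. Nothing in the labels says that the repeats came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

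The table held 35399 probe sets. The platform annotation gave 21789 of them exactly 1 gene symbol and 1621 several, and 11989 were not listed in it. Symbols of 21698 probe sets were matched through their Entrez identifier to RefSeq names of the assembly GRCm38.p6, which changed 0 symbols. Ratios were put on the log2 scale with no further centring and averaged per symbol, which gave 19938 genes, 999 of them from more than 1 probe set.

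Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a model without intercept that had a coefficient for each group. Each coefficient was tested against 0, which is equality with control, and their difference compared knockdown with rescue. All 4 columns shared the estimate of the spread, with 2 residual degrees of freedom and 6.11 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 19938 genes, with a threshold of 0.05. A test of a ratio against 0 takes the spread of the control array only as far as it differs between repeats, and the same control array stands under both groups of a repeat.

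Of 27 gene lists, fixed before the data were examined, 26 had at least 3 measured members and were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. In all, 584 of 648 list genes were measured. With a correlation estimated from the data, 0 lists passed in each comparison, and fry called 0. The camera test with an estimated correlation rested on the 2 residual degrees of freedom, and its smallest unadjusted p was 0.0445. It could hardly call any list, so a missed call there is weak evidence against a shift. The estimated correlations, themselves imprecise, lay above 0.01 for all lists but synaptotagmins (-0.0494) and heat shock genes (-0.0298). They reached 0.571 for activity-regulated genes and 0.627 for the interferon response. For lists so correlated, camera p-values at the preset correlation are too small and are weak evidence for a shift. The genes named were also fixed by rule: the measured calmodulin genes and synaptotagmins always, then 10 genes per direction for each comparison of the knockdown (5 for rescue against control), among those past the threshold with the same sign in both repeats, ranked by the smaller of their 2 repeat values. Where too few passed, genes below the threshold filled the places and are described as such. For each list, up to 4 members with the largest mean change could be named. Predicted genes, olfactory and vomeronasal receptors, small RNAs and receptor segments (2917 genes) were counted but not named.

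The labels give same-numbered samples a shared repeat day, so the numbers pair the samples. Deviations of same-numbered columns from their group means correlated across genes at 0.305, and a fit with the repeat as a block was run beside the unblocked one. The methods were tested on 20 simulated data sets of 19938 genes with shared control arrays, in which 200 genes had changed in the knockdown. For knockdown against control the unblocked fit recovered 73.7% of genes changed 2-fold and 97.1% of those changed 3-fold, with on average 4.5 false calls among 122. The block recovered 99.3% of those changed 2-fold, with 260 false calls among 444, because it also removes the spread of the control. For knockdown against rescue the unblocked fit recovered 3.13% of genes changed 2-fold and 72.9% of those changed 3-fold, with 0.1 false calls among 50.3. There the block recovered 90.1% of genes changed 2-fold, with 21.6 false calls among 161. The simulation gave control, knockdown and rescue arrays equal noise. Unchanged groups of a repeat then correlated at 0.495, above the 0.305 of the data, so its counts of false calls may not carry over.

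Alternatives covered centring, quantile normalization, every probe set in place of gene means, robust eBayes, a test against a fold of 1.2 (treat), a fit of the compared columns alone, a test without the unnamed classes, an estimated correlation for the lists, other fold limits and leaving out each column. A random block with 1 correlation pooled over genes (0.301) was added after the data were seen, because duplicateCorrelation could not be run with 4 columns. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.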

Results

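The data compare mouse cortical neuron cultures in which calmodulin was knocked down, or knocked down and replaced by an shRNA-resistant wild-type calmodulin, with control-infected cultures of the same repeat. Each group had 2 samples, read on whole-transcript arrays as ratios to control. Calmodulin is the main calcium sensor protein of neurons and is encoded by several genes. Ratios were spread most widely in knockdown repeat 2, with a standard deviation of 0.349 across genes on the log2 scale. It was 0.242 in knockdown repeat 1, 0.243 in rescue repeat 1 and 0.232 in rescue repeat 2.

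Calm2 and Calm3 were lower than control in every sample that carried the shRNAs. Calm2 was at -1.08 and -1.72 on the log2 scale in the 2 knockdown repeats and fell to a mean of -1.40 (SE 0.18, n = 2, limma adjusted p = 0.0297). Its 2 probe sets both lay below control in each sample. Calm3 was at -1.32 and -2.40 (mean -1.86, SE 0.30) and missed the threshold (adjusted p = 0.0577; 0.000284 with the repeat as a block). In the rescue Calm2 was at -0.84 and -1.28, and Calm3 at -2.41 and -3.55, without passing the threshold (adjusted p = 0.414 and 0.154; 0.0129 and 1.58e-05 with the repeat as a block). Whether these probe sets read the resistant construct is not given in the sources used here.

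The comparison of knockdown with control asked which transcripts change when calmodulin is depleted. Syt2, a fast calcium sensor of synaptic vesicle release found mainly in caudal brain regions, rose most. It stood 5.62-fold above control (log2 2.49, SE 0.12, n = 2, adjusted p = 0.000475), at 2.41 and 2.57 in the 2 repeats. In all, 61 genes passed, 27 higher and 34 lower. Genes that rose included Vamp1, a vesicle SNARE, Nefh, the heavy neurofilament chain, and Map1a, a microtubule-associated protein. Genes that fell included Homer1, a postsynaptic scaffold, Hpca, the calcium sensor hippocalcin, and Cacna1i, a T-type calcium channel.

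Among the genes that rose after Syt2, Coro6 stood 3.93-fold above control (adjusted p = 0.00392) and Vwa5b2 2.84-fold (adjusted p = 0.00998). Vamp1 rose 2.82-fold, Nefh 2.75-fold, Maged2 2.69-fold, Flt3 2.55-fold and Map1a 2.41-fold, each with an adjusted p below 0.05. Peg10 rose 3.86-fold and Scn4b, a sodium channel beta subunit, 3.97-fold, but their repeats differed (1.29 and 2.61, and 1.21 and 2.77, on the log2 scale; adjusted p = 0.0412 and 0.0491). Of the genes past the threshold Tafa1 fell most (log2 -1.61, adjusted p = 0.00998), and other genes that fell included Nwd2 (-1.54, adjusted p = 0.00998), Pak6 (-1.37, adjusted p = 0.00998) and Hpca (-1.31, adjusted p = 0.0140). Slit1, an axon guidance ligand, fell to -1.35, Gpr26 to -1.29, Kcnq3, a subunit of the M-current channel, to -1.12, Cacna1i to -1.11 and Homer1 to -1.09.

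**Figure D1:**
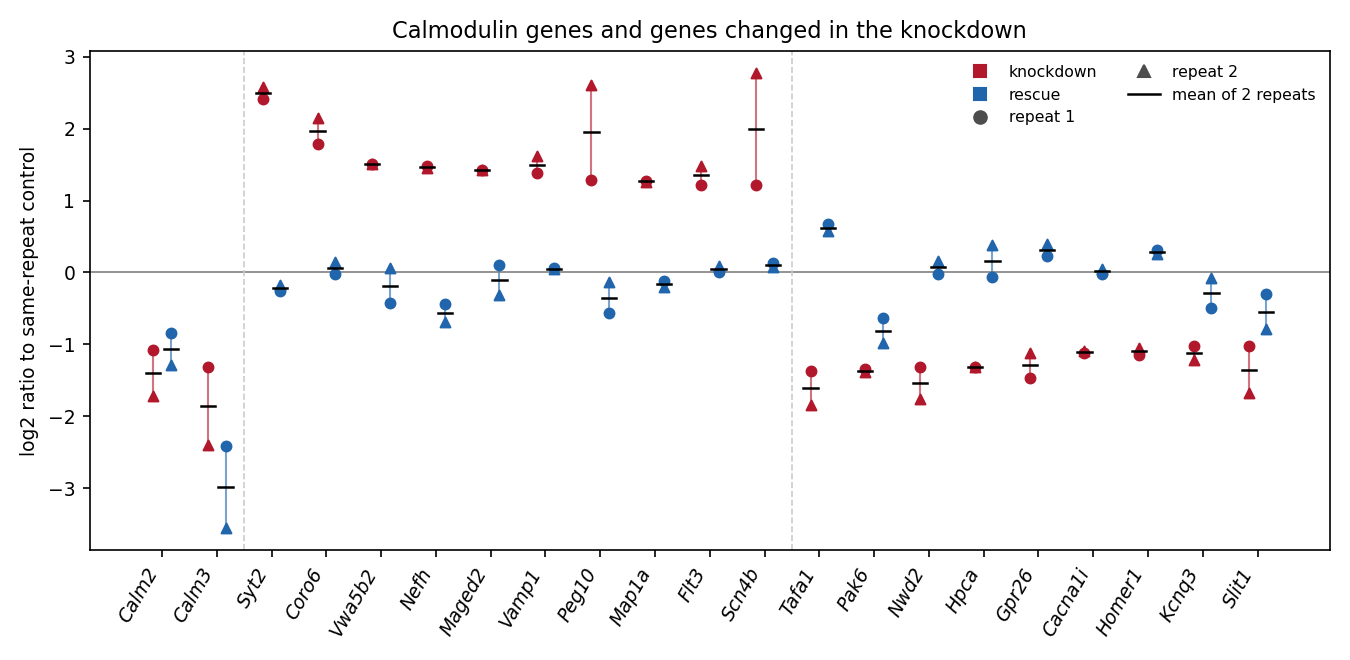
Log2 ratio to the control of the same repeat for Calm2, Calm3 and the genes named for knockdown against control, in knockdown (red) and rescue (blue) samples. Circles are repeat 1, triangles repeat 2 and black bars the mean of 2 repeats. Syt2 lies at 2.41 and 2.57 in the knockdown and at -0.25 and -0.17 in the rescue.

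Of 17 synaptotagmins measured, Syt2 passed the threshold over all genes. Adjusted over the list alone, 2 were higher and 5 lower. Syt5 was at -0.66 (adjusted p = 0.0737), Syt4 at -0.63 (0.0893), Syt16 at -0.63 (0.146, with -0.39 and -0.88 in the repeats) and Syt7 at -0.58 (0.0912). With the repeat as a block 1 was higher and 3 lower. Syt1 was at -0.27 (adjusted p = 0.370, with -0.08 and -0.46 in the repeats), and Syt12 at 0.60 (0.16 and 1.05), also not past the threshold. Values of the others, with the repeats in brackets where they lay apart, were -0.25 for Syt3 (-0.02 and -0.47), 0.21 for Syt6 (0.12 and 0.29), 0.13 for Syt8 (0.06 and 0.19), -0.20 for Syt9, -0.13 for Syt10 (-0.32 and 0.06), -0.02 for Syt11 (0.16 and -0.20), -0.10 for Syt13 (0.00 and -0.21), -0.41 for Syt14 (-0.25 and -0.56), 0.07 for Syt15 (-0.08 and 0.22) and -0.58 for Syt17 (-0.37 and -0.79). Syt11 turned to 0.01 under quantile normalization.

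Lists of synaptic genes lay below control. Of 35 genes of the vesicle release machinery, 1 rose (Vamp1) and 0 fell over all genes, while 4 were higher and 19 lower adjusted over the list alone (4 and 14 over all genes with the repeat as a block). Erc2, an active zone scaffold, was at -1.17 (-0.74 and -1.60 in the repeats) and Doc2b, a calcium-binding protein of exocytosis, at -1.04 (-0.56 and -1.53). The vesicular glutamate transporter Slc17a6 was at 1.04 (0.66 and 1.42), and none of these passed the threshold. The list median was -0.41 (camera adjusted p = 5.44e-08; adjusted p = 0.557 with an estimated correlation) and -0.25 without knockdown replicate 2. Of 30 glutamate receptor and scaffold genes 0 passed over all genes, and 13 were lower adjusted over the list alone (10 over all genes with the block), with Grm5 at -0.91 and Grin2a at -0.89. Their median was -0.40 (camera adjusted p = 1.11e-08; adjusted p = 0.557 with an estimated correlation).

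Among 41 voltage-gated channel genes, 1 rose (Scn4b) and 3 fell (Cacna1i, Kcnq3 and Kcnq5, the last to -0.98), and 3 were higher and 16 lower adjusted over the list alone (2 and 11 over all genes with the block). The median was -0.33 (camera adjusted p = 1e-07; adjusted p = 0.563 with an estimated correlation) and -0.22 without knockdown replicate 2. Of 36 calmodulin effectors and binding proteins 0 passed over all genes, and 1 was higher and 13 lower adjusted over the list alone (1 and 8 with the block). Ppp3ca, the catalytic subunit of calcineurin, was at -1.24 (-0.82 and -1.66 in the repeats), just short of the threshold, and Itpka at -1.17 (adjusted p = 0.0548). This median was -0.25 (camera adjusted p = 1.01e-06; adjusted p = 0.557 with an estimated correlation).

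Cortical excitatory neuron markers had a median of -0.41 (camera adjusted p = 3.34e-06; adjusted p = 0.557 with an estimated correlation). Of 16, 0 passed over all genes and 7 were lower adjusted over the list alone (6 with the block), with Neurod6 at -1.65 (-0.81 and -2.49 in the repeats) and Slc17a7 at -0.80. Parvalbumin and caudal fast-synapse markers went the other way. Of 14, Scn4b, Vamp1 and Nefh rose and 0 fell, and 6 were higher and 1 lower adjusted over the list alone (5 and 1 with the block). Their median was 0.34 (camera adjusted p = 0.000380; adjusted p = 0.563 with an estimated correlation) and 0.21 without knockdown replicate 2. Astrocyte markers had a median of 0.25 in the same samples (camera adjusted p = 2.88e-06; adjusted p = 0.557 with an estimated correlation), with 0 of 19 past the threshold over all genes, 0 adjusted over the list alone and 3 higher with the block. Sox9 was at 0.44 and Gja1 at 0.45. Endothelial and fibroblast markers had medians of 0.11 and 0.18 (camera adjusted p = 0.00839 and 0.0128; adjusted p = 0.563 for both with an estimated correlation). Both calls rested on knockdown replicate 2, without which the medians were 0.04 and 0.02 (camera adjusted p = 0.544 and 0.650), and without knockdown replicate 1 they were 0.39 and 0.33. Microglia markers had a median of -0.14 (camera adjusted p = 0.233), or -0.34 without knockdown replicate 2 (camera adjusted p = 7.68e-05).

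Cholesterol synthesis genes lay below control as a group. All 19 measured had a mean below 0. Over all genes 0 passed, and 12 were lower adjusted over the list alone (11 over all genes with the block). Hmgcs1, which makes the precursor of mevalonate, was at -1.12 (-0.62 and -1.63 in the repeats), Fdft1 at -0.88 (-0.47 and -1.28) and Sqle, squalene epoxidase, at -0.84. The list median was -0.49 (camera adjusted p = 4.66e-11; adjusted p = 0.563 with an estimated correlation) and -0.75 without knockdown replicate 1.

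The count of 61 depended on the fit. It was 1074 with the repeat as a block, a fit that made many false calls against control in simulation, 20 (13 higher, 7 lower) after quantile normalization and 0 with every probe set tested, where Syt2 had the smallest adjusted p (0.105). It was 1272 without knockdown replicate 1, 108 without knockdown replicate 2 and 12 without either rescue replicate. A count by size alone gave 16 genes at least 2-fold above control in both repeats, 16 at least 2-fold below and 1 with opposite signs. The 2 repeats could also be read against each other, since each had its own control array. Of 20 genes at least 2-fold above control in repeat 1, 20 were above it in repeat 2 (median 1.43), and of 49 below, 38 were below (median -0.49). Of 105 above in repeat 2, 78 were above in repeat 1 (median 0.24), and of 192 below, 176 were below (median -0.47).

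The comparison of rescue with control asked how near to control the cultures came when a resistant calmodulin was supplied with the shRNAs. No gene passed the threshold in limma (0 of 19938, smallest adjusted p = 0.154), with 1484 genes at an unadjusted p under 0.05. With the repeat as a block 25 passed, 12 higher and 13 lower. In the simulation, where the rescue was unchanged, that fit made 124 calls on average. A fit of the rescue columns alone called 176, and leaving out either knockdown replicate amounts to that same fit. At least 2-fold in both repeats, 4 genes were above and 3 below control.

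Genes far from control in both rescue repeats, none past the threshold, included Ptgs2, the inducible cyclooxygenase (log2 2.28, adjusted p = 0.328; 0.00898 with the block), and the neuropeptide genes Grp (2.82-fold above control, adjusted p = 0.464) and Penk (log2 1.27, adjusted p = 0.414; 0.0493 with the block). Trpc6 was at 1.37 and Slc7a3 at 1.36 (0.00898 and 0.00984 with the block). Below control were Calm3 at -2.98, Ppp3ca at -1.38 and Nptx1 at -1.39 (0.0190 and 0.0176 with the block for the last pair), Nr3c2 at -0.88 and Kit at -0.86. Pak6, which fell in the knockdown, was at -0.81 in the rescue.

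Activity-regulated genes, the transcripts induced by neuronal firing, had a rescue median of 0.30 (camera adjusted p = 5.17e-10; adjusted p = 0.923 with an estimated correlation). Of 42, 0 passed over all genes and 5 were higher adjusted over the list alone (3 with the block), with Inhba at 1.26 (1.93 and 0.59 in the repeats) and Npas4 at 1.12 (0.54 and 1.70). Interneuron markers had a median of -0.28 (camera adjusted p = 5.14e-06; adjusted p = 0.923 with an estimated correlation), with 0 of 18 past and 5 lower adjusted over the list alone (1 with the block), among them Gad1 at -0.87. The interneuron median was -0.53 without rescue replicate 1 and -0.26 without rescue replicate 2, where the call was lost (camera adjusted p = 0.0738). Microglia and macrophage markers had a median of -0.20 (camera adjusted p = 0.00137; adjusted p = 0.923 with an estimated correlation) and cholesterol synthesis genes one of 0.17 (camera adjusted p = 0.00144; adjusted p = 0.923 with an estimated correlation), both with 0 members past over all genes, adjusted over the list alone or with the block. Without rescue replicate 1 these medians were -0.14 and 0.15 and neither was called (camera adjusted p = 0.473 and 0.0575), and without rescue replicate 2 the microglia median was -0.36.

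The comparison of knockdown with rescue asked which transcripts differed with and without the resistant calmodulin, since both groups carried the shRNAs. Syt2 was 6.51-fold higher in the knockdown (log2 2.70, SE 0.17, n = 2 per group, adjusted p = 0.00387). In all, 14 genes differed, 8 higher and 6 lower in the knockdown. Nefh was 4.07-fold higher (adjusted p = 0.0228) and Coro6 3.75-fold (adjusted p = 0.0373). Tafa1 was at -2.23 (adjusted p = 0.0247). The other 10 genes shared an adjusted p of 0.0499. They were Vwa5b2 (3.22-fold), Lgi3 (3.02-fold), Vamp1 (2.72-fold), Map1a (2.69-fold) and Cntnap1 (2.68-fold), higher in the knockdown, and Acvr1c (-1.77), Gpr26 (-1.60), Sema4a (-1.54), Homer1 (-1.38) and Cpne5 (-1.37), lower. Some of the 14 differences held a shift of the rescue from control, opposite to that of the knockdown. Rescue means were 1.00 for Acvr1c, 0.66 for Sema4a, 0.62 for Tafa1, -0.56 for Nefh and -0.52 for Lgi3, none past the threshold. Others lay nearer to control in the rescue, among them Coro6 at 0.07 and Vamp1 at 0.05.

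Just outside the threshold were Maged2 (log2 1.53, adjusted p = 0.0515) and Ptgs2 (-2.81, adjusted p = 0.0748), and farther from it Kcnv1 (-1.98, adjusted p = 0.0991), Peg10 (2.30), Neurod6 (-2.01, adjusted p = 0.351) and Npas4 (-2.21, adjusted p = 0.360). All of these passed with the repeat as a block, which called 123 genes, 37 higher and 86 lower. The 14 genes all remained among those 123. Calm3 was 1.12 higher on the log2 scale in the knockdown than in the rescue (adjusted p = 0.613; 0.0169 with the block), and Calm2 differed by -0.34 (adjusted p = 1.00).

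**Figure D2:**
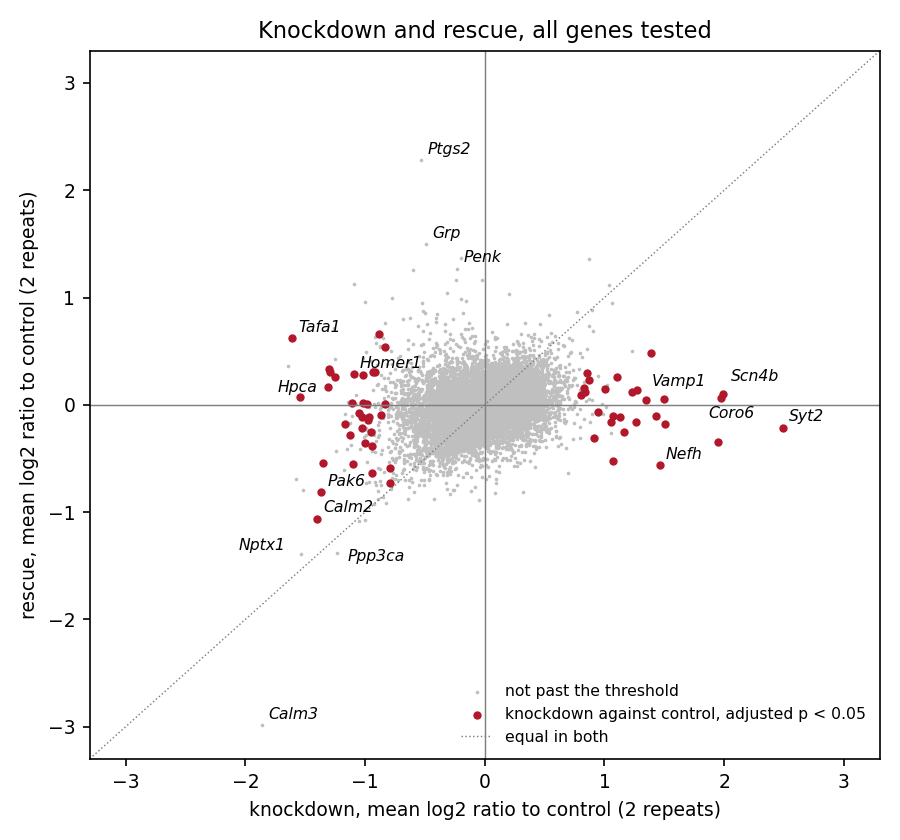
Mean log2 ratio to control of each gene in the knockdown (horizontal axis) and in the rescue (vertical axis), over 2 repeats each. Red points are the 61 genes past the threshold in the knockdown, and the dotted line marks equal values. The red points above 0 on the horizontal axis have a median of 1.17 in the knockdown and 0.05 in the rescue.

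Most genes that had changed in the knockdown lay within 1.5-fold of control in the rescue. Of 27 that rose, 27 were within 1.5-fold of control in the rescue (median log2 0.05), and of 34 that fell, 27 were (median -0.09). The limit is wide beside the spread of all genes in the rescue (standard deviations 0.243 and 0.232 on the log2 scale), so most genes meet it whether changed or not. Part of the likeness of both groups comes from their shared control arrays. Read across repeats, where no control is shared, genes at least 2-fold above control in knockdown repeat 1 had a median of 0.04 in rescue repeat 2, and those below it had one of 0.39. Genes chosen in knockdown repeat 2 had medians of 0.04 and -0.23 in rescue repeat 1, and 143 of the 192 chosen as low were below 0 there.

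Across genes, which are not independent replicates, knockdown and rescue ratios correlated at 0.325 and 0.322 within a repeat (covariance 0.0192 and 0.0260). Simulated unchanged groups that shared their controls gave 0.495 (covariance 0.0254). Between repeats the correlations were -0.00526 for knockdown repeat 1 with rescue repeat 2 and 0.175 for the reverse (covariance -0.000296 and 0.0148), against 0.00392 in simulation (covariance 0.000204).

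Among gene groups, cholesterol synthesis genes had a median of -0.71 in the knockdown against the rescue (camera adjusted p = 4.87e-19; adjusted p = 0.472 with an estimated correlation), or -0.47 without knockdown replicate 2, with 0 of 19 past over all genes and 14 lower adjusted over the list alone (5 with the block). Activity-regulated genes had a median of -0.49 (camera adjusted p = 2.61e-14; adjusted p = 0.472 with an estimated correlation). The median was -1.02 in repeat 1 and -0.03 in repeat 2. It was -0.15 without knockdown replicate 1, still called (camera adjusted p = 0.000364), and -0.999 without knockdown replicate 2. Of these 42, Homer1 was lower and 11 were lower adjusted over the list alone (9 with the block), with Arc at -1.96. Glutamate receptor genes had a median of -0.26 (camera adjusted p = 2.09e-07; adjusted p = 0.472 with an estimated correlation), or -0.46 without knockdown replicate 1, with 0 past over all genes and 7 lower adjusted over the list alone (2 with the block), among them Cacng3 at -1.48.

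Vesicle release genes had a median of -0.31 (camera adjusted p = 1.71e-07; adjusted p = 0.472 with an estimated correlation), with Vamp1 higher and, adjusted over the list alone, 1 higher and 1 lower. Parvalbumin and caudal fast-synapse markers had a median of 0.33 (camera adjusted p = 3.11e-05; adjusted p = 0.472 with an estimated correlation), with Nefh and Vamp1 higher and, adjusted over the list alone, 3 higher and 1 lower (3 and 0 with the block). This median was 0.63 without rescue replicate 1 and 0.22 without rescue replicate 2. Astrocyte markers had a median of 0.30 (camera adjusted p = 6.6e-08; adjusted p = 0.472 with an estimated correlation), with 0 past over all genes, 2 higher adjusted over the list alone and 0 with the block. The unadjusted p of the astrocyte list with an estimated correlation was 0.0445. Microglia markers had a median of 0.10 (camera adjusted p = 0.104; 0.0266 with the block), or 0.30 without knockdown replicate 1 and 0.31 without rescue replicate 2 (camera adjusted p = 0.000317 and 0.00113).

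Some lists called against control were not called here. Interneuron markers, at -0.28 in the knockdown against control (camera adjusted p = 0.000380; adjusted p = 0.563 with an estimated correlation), had a median of 0.07 against the rescue (camera adjusted p = 0.935). The value was -0.27 without knockdown replicate 1 and 0.405 without knockdown replicate 2 (camera adjusted p = 0.000184 and 5.27e-05). Against control it was -0.62 without knockdown replicate 1, 0.13 without knockdown replicate 2 (camera adjusted p = 0.787) and -0.16 after quantile normalization. Inflammation genes had a median of 0.11 against the rescue (camera adjusted p = 0.298), or 0.17 without knockdown replicate 1 and -0.05 without knockdown replicate 2 (camera adjusted p = 0.00488 and 0.0188).

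**Figure D3:**
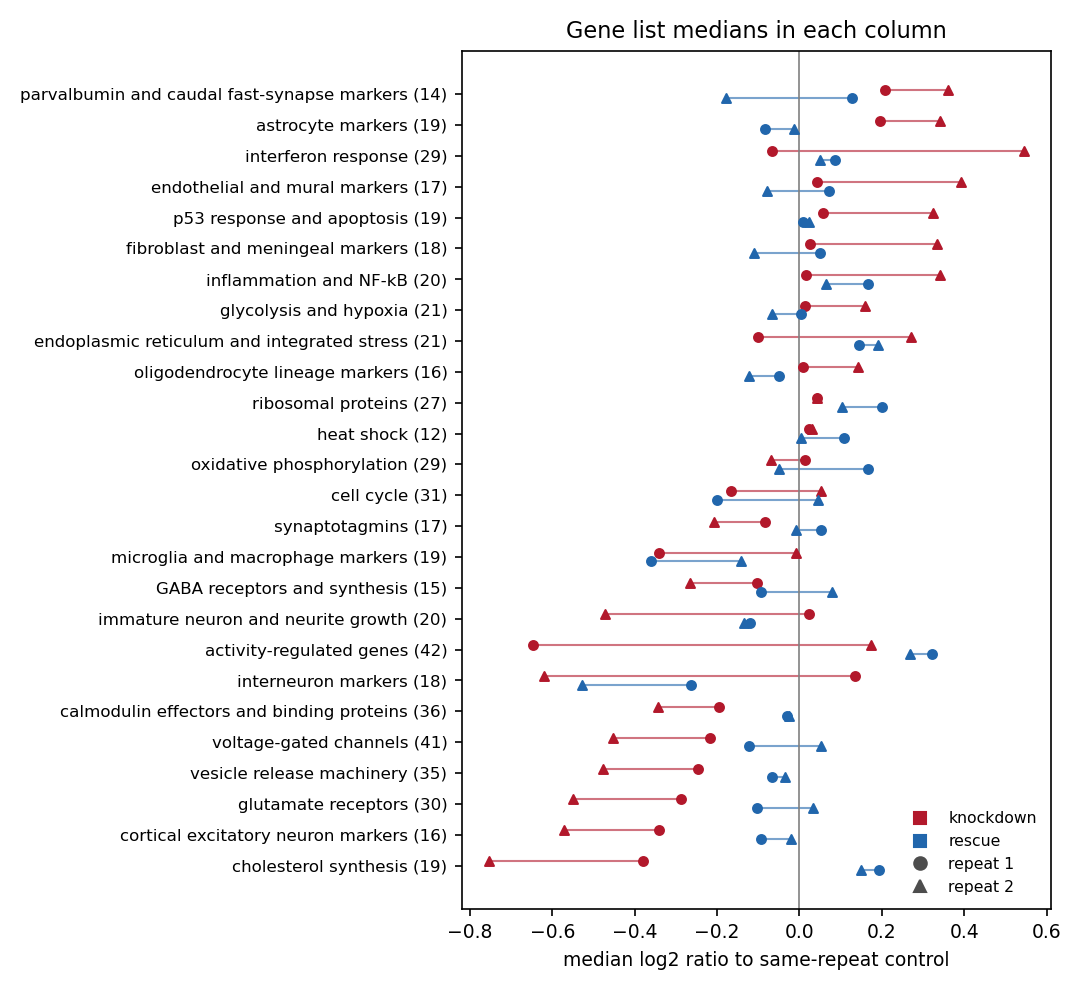
Median log2 ratio to the control of the same repeat for each gene list, with the number of measured genes in brackets. Red is knockdown, blue is rescue, circles are repeat 1 and triangles repeat 2. Cholesterol synthesis genes lie at -0.38 and -0.75 in the knockdown and at 0.19 and 0.15 in the rescue, while activity-regulated genes lie at -0.65 and 0.17 in the knockdown.

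The count of 14 also moved with the fit. Centring left 4 (3 higher, 1 lower), quantile normalization 2 and every probe set 0. It was 350 without knockdown replicate 1, 147 without knockdown replicate 2 and 0 without either rescue replicate. At least 2-fold in both repeats, 21 genes were higher and 40 lower in the knockdown than in the rescue, and 4 had opposite signs.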

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

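The genes here were picked out by the planned test of knockdown against rescue, and the count of unnamed probe sets was chosen after the data were seen. In 14 genes the response to the shRNAs differed with and without the resistant calmodulin, 10 of them at an adjusted p of 0.0499. These calls depended on the fit. Of the 14, 4 were kept after centring, 4 with robust eBayes, 3 under treat, 2 after quantile normalization, and 0 with every probe set or without either rescue replicate. The knockdown minus rescue difference on the log2 scale was 2.70 for Syt2, 2.02 for Nefh, 1.90 for Coro6, 1.69 for Vwa5b2, 1.60 for Lgi3, 1.44 for Vamp1, 1.43 for Map1a and 1.42 for Cntnap1. It was -2.23 for Tafa1, -1.77 for Acvr1c, -1.60 for Gpr26, -1.54 for Sema4a, -1.38 for Homer1 and -1.37 for Cpne5. Acvr1c missed the threshold against control in the knockdown (log2 -0.77, with -1.06 and -0.48 in the repeats, adjusted p = 0.0857). Its mean in the rescue was 1.00, farther from control than in the knockdown.

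Probe sets outside the gene test were counted by size alone, without a test. Of 13610 probe sets without exactly 1 gene symbol, 10 were at least 2-fold above control in both knockdown repeats and 7 at least 2-fold below, and in the rescue 3 were above and 7 below. These probe sets have no gene name here.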

How the results depend on the processing

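All settings were chosen before the data were examined except the random block with a pooled correlation; duplicateCorrelation was not run, since it needs more columns. The number of genes called was the least stable result. For knockdown against control, 61 became 20 after quantile normalization, 0 with every probe set, 13 under treat, 12 with the compared columns alone, 117 without the unnamed classes, 1074 with the replicate block and 103 with the random block, and ranged from 12 to 1272 when a column was left out. For rescue against control, 0 became 1 after quantile normalization, 25 with the replicate block, 1 with the random block and 176 with its columns alone, and ranged from 0 to 176 when a column was left out. For knockdown against rescue, 14 became 4 after centring, 2 after quantile normalization, 0 with every probe set, 4 with robust eBayes, 3 under treat, 22 without the unnamed classes, 123 with the replicate block and 91 with the random block, and ranged from 0 to 350 when a column was left out. Leaving out a knockdown column takes the spread from the rescue pair alone, and the lone sample is assumed to vary like it. In the same way, leaving out a rescue column takes the spread from the knockdown pair alone. For the pair that stays complete, the test against control is then that of the compared columns alone. Other causes of the moving counts were not tested. Of the 61 genes, 61 were kept with either block, 55 after centring, 19 after quantile normalization and 11 under quantile normalization, compared columns alone, treat, centring and robust eBayes together, namely Coro6, Flt3, Maged2, Map1a, Nefh, Nwd2, Pak6, Syt2, Tafa1, Vamp1 and Vwa5b2.

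Of 26 lists, 18, 8 and 16 passed for knockdown against control, rescue against control and knockdown against rescue. With an estimated correlation 0, 0 and 0 did, and 10 to 19 passed for knockdown against control when a column was left out. With the replicate block 18, 8 and 17 did. When a column was left out, medians against control ranged from -0.647 to 0.173 for activity-regulated genes, from -0.62 to 0.134 for interneuron markers, from -0.0661 to 0.545 for the interferon response (-0.0659 to 0.392 against rescue) and from -0.473 to 0.0224 for immature neuron genes in the knockdown, and from -0.201 to 0.0453 for the cell cycle in the rescue. The sign turned without knockdown replicate 1 for activity-regulated genes, without rescue replicate 1 for the cell cycle and without knockdown replicate 2 for the others. In the knockdown Syt10 ranged from -0.316 to 0.0562, Syt11 from -0.195 to 0.161 (0.0118 after quantile normalization) and Syt15 from -0.0838 to 0.224; none of them was called.

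Counts of genes at least 2-fold from control in both repeats were 32 for the knockdown (20 after quantile normalization, 51 with every probe set, 207 at 1.5-fold), 7 for the rescue (13, 17 and 68) and 61 between knockdown and rescue (295 at 1.5-fold). Medians in the repeat not used to choose the genes, averaged over both directions of reading, were 0.0414 in the rescue for genes that were high in the knockdown (0.0623 after centring, 0.0585 after quantile normalization, 0.134 with every probe set, 0.0136 at 1.5-fold), 0.836 in the knockdown for those high genes (0.189 with every probe set, 0.266 at 1.5-fold), -0.48 in the knockdown for low genes (-0.555 after quantile normalization, -0.197 with every probe set, -0.42 at 1.5-fold) and 0.0783 in the rescue for low genes (-0.0192 at 1.5-fold, a change of sign). The mean correlation of knockdown with rescue was 0.323 within a repeat (0.328 after quantile normalization, 0.453 with every probe set, 0.527 over genes beyond 1.2-fold) and 0.0848 between repeats (0.414 over genes beyond 1.2-fold). Genes beyond 1.2-fold were chosen by their mean over all knockdown and rescue columns. That choice by itself raises the correlation, so the higher values show no greater likeness of the groups. Signal over background could not be weighed, since ratios carry no intensity.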

Other observations

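All tests of explanations in this part were chosen after the results they concern had been seen, at least in part. Other gene lists, fixed before the data were examined, moved less evenly. In the knockdown, genes of the p53 response and apoptosis had a median of 0.27 (camera adjusted p = 0.000995; adjusted p = 0.563 with an estimated correlation), with Fas at 0.73 (0.34 and 1.13 in the repeats), and inflammation genes one of 0.18 (camera adjusted p = 0.00123; adjusted p = 0.563 with an estimated correlation), with Cp at 0.69 (0.31 and 1.06 in the repeats). Neither list had a member past the threshold over all genes, and both calls rested on knockdown replicate 2, without which the medians were 0.06 and 0.02 (camera adjusted p = 0.305 and 0.878). Without knockdown replicate 1 the inflammation median was 0.34. GABA receptor and synthesis genes had a median of -0.24 (camera adjusted p = 0.00492; adjusted p = 0.563 with an estimated correlation), with Gad1 at -0.89. Glycolysis and hypoxia genes had a median of 0.14 (camera adjusted p = 0.0446; adjusted p = 0.584 with an estimated correlation). Without knockdown replicate 2 these medians were -0.10 and 0.01, and neither was called (camera adjusted p = 0.394 and 0.949). With every probe set tested the GABA median was -0.12, and the call of glycolysis and hypoxia genes was lost, as it was after quantile normalization. Interneuron markers held Cck, a neuropeptide gene that fell to -1.25 (adjusted p = 0.0219), and immature neuron genes held Cntn2, an axonal adhesion molecule that rose to 1.13 (adjusted p = 0.0397).

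Lists whose knockdown repeats lay on opposite sides of control were the interferon response (-0.07 and 0.55), interneuron markers (0.13 and -0.62), immature neuron genes (0.02 and -0.47), endoplasmic reticulum stress (-0.10 and 0.27), the cell cycle (-0.17 and 0.05), oxidative phosphorylation (0.01 and -0.07) and activity-regulated genes (-0.65 and 0.17). Medians of heat shock genes (0.03), ribosomal proteins (0.04), oxidative phosphorylation genes (-0.01) and oligodendrocyte markers (0.02) were not distinguishable from other genes in the knockdown (camera adjusted p = 0.284, 0.483, 0.774 and 0.721). In the rescue, ribosomal proteins had a median of 0.12 (camera adjusted p = 0.000198) and endoplasmic reticulum stress genes one of 0.14 (camera adjusted p = 0.000532), both with an adjusted p of 0.923 with an estimated correlation. Without rescue replicate 2 the ribosomal median was 0.20, and the endoplasmic reticulum stress call was lost (camera adjusted p = 0.0741, median 0.14).

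Synaptic and channel lists were low and astrocyte markers high in the knockdown, which may reflect fewer neurons or a general rise of other cells. A pan-neuronal list of 22 genes had a median of -0.235 (-0.0689 and -0.356 in the repeats), against -0.288 and -0.549 for glutamate receptors, which leaves a loss of neurons open. In the rescue the pan-neuronal medians were -0.0625 and -0.069, near that of knockdown repeat 1. The list shared Snap25, Syn1, Syp and Dnm1 with the vesicle release list, so it is not an independent gauge of neuron number. Markers of 5 non-neuronal cell types spread over a range of 0.393 in their medians against control (permutation p = 8e-04, 85 genes) and 0.226 against the rescue (permutation p = 0.0873), so a general rise stays open too. The permutation shuffled markers as if independent, though estimated correlations within the lists ran from 0.0489 (astrocyte) to 0.409 (endothelial). Its p-values may therefore be too small. That test replaced 2 earlier versions, a sign count that rested on a microglia median of -0.00729 in knockdown repeat 2, and a comparison of astrocyte with microglia markers alone (permutation p = 0.0032 against the rescue), set aside because that pair had been picked for its medians. An effect of calmodulin on transcription in neurons was not tested apart from these.

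Some genes were low in the knockdown and in the rescue, which chance in the shared control arrays could produce. At least 1.5-fold below control in all 4 columns were 10 genes (Atp6v1e1, Calm2, Calm3, Cdh12, Gad1, Grm5, Lor, Nptx1, Pak6 and Ppp3ca), and 1 was above (Slc17a6), against at most 1 below in 100 simulated data sets without change. A check added after that simulation took genes low in both columns of a repeat and read them in the other repeat. That repeat has its own control array, and its knockdown and rescue values were averaged. The medians were -0.614 (40 genes) and -0.331 (103 genes), below random lists (2.5th percentiles -0.0756 and -0.0593). Genes lowered in the knockdown alone could give these medians, and the simulation held no such genes. Calm2 and Calm3 are targets of the shRNAs, which both groups carried, so their low values have a source in the design. For the other genes, control array noise as a cause of the low rescue values stays open. Effects of the shRNAs on those other genes that the construct did not reverse stay open too and were not tested.

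Activity-regulated genes were at -0.647 in knockdown repeat 1 and 0.173 in knockdown repeat 2, with 0.321 and 0.269 in the rescue. A control array of repeat 1 with high levels of these transcripts would lower the rescue of that repeat as well, yet its median was 0.321 (bootstrap interval over genes 0.233 to 0.469, 37 of 42 genes above 0). The interval resampled correlated genes of that sample as if independent, and the high rescue was part of the pattern that prompted the check. The control cancels in knockdown minus rescue within a repeat, and that list median was -1.02 in repeat 1 and -0.03 in repeat 2. A high control array therefore cannot account for the gap between knockdown and rescue in repeat 1. That it lowered both values of that repeat against control is not excluded. The median over genes of the difference between repeats (repeat 1 minus repeat 2) was -0.853 in the knockdown and 0.116 in the rescue. The knockdown shift exceeded that of 100% of 10000 random lists, which decides nothing, since the list was examined because of this shift and its members were correlated (estimated correlation 0.571). Whether the knockdown cultures of the repeats differed in these transcripts stays open, and with 2 repeats the direction of this list in the knockdown is not settled.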
